A study of Homo sapiens with 8 samples.

How the data were processed

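Total RNA of 8 samples of Huh7, a line derived from a human hepatocellular carcinoma, was measured on 4 Agilent 2-colour microarrays. Per the labels' protocols, the RNA was extracted with Trizol and the cDNA was labelled with Cy3-dCTP or Cy5-dCTP by Klenow fragment. The labels give 4 control samples, 2 samples with a knockout of the long non-coding RNA HAND2-AS1 and 2 samples with a short hairpin RNA against INO80. The files of a control and of a perturbed sample were identical in pairs, so each pair was 1 array with the control in Cy3 and the perturbed sample in Cy5. Controls 1 and 2 shared slide 1 with knockout replicates 1 and 2, and controls 3 and 4 shared slide 2 with knockdown replicates 1 and 2. No array had the dyes swapped, so a dye bias of a probe is part of each comparison with control, and it cancels between the perturbations only where it is equal on all arrays. Slide and perturbation cannot be told apart in the comparison of the knockout with the knockdown.

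The deposited scanner files hold spot intensity values that are not normalized, per the file headers, as extracted with Agilent Feature Extraction 11.5.1.1. They also hold the scanner software's processed signals, which are background-subtracted and dye-normalized, and flags for spots well above background, saturated spots and outliers. The series matrix deposited by the authors holds log2 values of 75206 probes; the submitters' processing notes name limma without a version. From their values these columns were quantile-normalized over the 8 channels, with a median of 6.80 in each column, and their rank correlations with the processed signal of their own channel ran from 0.9985 to 0.9993. Any centring before that stays unknown, and no direction applies because each column is 1 channel.

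The design assumed mean spot signals, and median spot signals were used in their place. Background was corrected with normexp (offset 50) on the median signal and the median local background. The log2 ratio of Cy5 over Cy3 was normalized by loess within each array, with control spots and spots flagged as outliers at weight 0. Outlier spots were then left out, and spots of a probe were averaged. Of 75149 non-control probes, 49541 had 2 spots and 25608 had 3 spots. Probes with no usable spot on some array numbered 74 and were left out. A probe was tested when it was well above background in at least 2 of the 8 channels, which left 60743 probes. A channel counted for a probe when at least 50% of its spots were well above background.

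Each perturbation had its own mean in 1 linear model over the 4 arrays, fitted with lmFit and eBayes of limma 3.58.1 under R 4.3.3, with 2 residual degrees of freedom and a prior of 3.28. The 3 comparisons were the knockout against control, the knockdown against control, and the knockout ratio minus the knockdown ratio. Tests were two-sided, and a probe was called at a Benjamini-Hochberg adjusted p of 0.05. The number of arrays limits the precision. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Log ratios of the 60743 probes were simulated with independent normal noise, at the variance that eBayes gave each probe. With 200 probes changed in the knockout comparison, the fit recovered 94.0% of the 2-fold changes and 100.0% of the 4-fold changes, with 28 false calls. These false calls were a larger share of the calls than the threshold of 0.05. The variances from eBayes are drawn towards a common value, so the simulated spread is not that of the arrays and gives no error rate for the data.

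The scanner files name probes by identifiers only, and no table used here pairs these with genes. The 32 gene lists fixed before the data were examined, among them HAND2-AS1 and INO80 themselves, matched no probe identifier and were not analysed here, nor were the unit of 1 probe per gene and the rule for named genes that rest on symbols. The results are therefore counts of probes, and the level of the targeted genes was not checked. In place of genes, the probe with the highest and the probe with the lowest log2 ratio was named for each comparison with control, a number reduced to 1 per direction after values had been seen, by the rest of the fixed rule: called, the same sign on both arrays, and well above background in all 4 channels compared. Probe classes were read from the probe names after the data had been examined: 18 classes, 15 of them with at least 5 tested probes. These 15 were tested with camera in limma at a preset correlation of 0.01, and again with camera at an estimated correlation and with fry. The human control probes for GAPDH and PGK1, 1 near the 5' and 1 near the 3' end of each transcript with 10 spots each, were tested in the same model, with 12 tests adjusted together. E1A spike-in probes (10) and control probes for mouse and rat genes were kept as checks.

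Values of single channels came from the loess ratios and the array's mean intensity after quantile normalization of the latter (Aquantile). The spot noise of a pair of samples was taken from single-channel quantile-normalized values, as the spread between the spots of a probe of the difference between the samples at the same spot. For probes well above background on one side only, the dim samples were set at their own value or at the lowest value well above background in their channel, whichever was higher, which makes the difference a lower bound. Alternatives were the background correction, the normalization, the filter, the variance model, the arrays in the fit, a 2-fold minimum, separate channels, the series matrix values and each array left out. The alternatives with probes averaged per gene, the log2 ratios of the targeted genes and the fixed gene lists were not run for want of gene names. A comparison with the other slide's controls and a fit with control pairs averaged were added after the data had been examined.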

Results

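RNA levels were profiled in Huh7 liver cancer cells after a knockout of HAND2-AS1, a long non-coding RNA transcribed beside the transcription factor gene HAND2, and after a short hairpin RNA knockdown of INO80, the ATPase of a chromatin remodelling complex. The design sets each perturbation against control cells on 2 arrays, and the title of the series places it in work on liver cancer stem cells. There were 4 control samples, 2 knockout samples and 2 knockdown samples. The array carries probes for tRNA, snoRNA and scaRNA, snRNA, rRNA and other small RNA classes beside catalogue and custom probes whose genes the files do not name. The share of spots well above background was 75.6% and 78.1% in controls 1 and 2, 51.4% and 64.6% in controls 3 and 4, 71.0% and 73.3% in the knockout samples, and 68.7% and 71.6% in the knockdown samples. Median raw intensity ranged from 94.7 to 145 over the samples, against 24.3 to 41.8 for the negative control probe. No spot of a non-control probe was saturated.

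Replicates were compared before they were averaged. The standard deviation of the probe differences was 0.15 (log2) between controls 1 and 2, against 0.10 from the noise between spots. Between controls 3 and 4 it was 0.12 against 0.11. The knockout replicates differed by 0.38 against 0.11 from spot noise, and the knockdown replicates by 0.24 against 0.09. The samples were kept separate as the labels count them; a spread beyond spot noise does not tell separate cultures from repeats of 1 RNA. Across probes, the log2 ratios of the knockout arrays correlated at a Pearson r of 0.81 and those of the knockdown arrays at 0.89; probes are not independent replicates.

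In the HAND2-AS1 knockout, probes for tRNA, the adaptors of translation, were higher than in the controls of the same slide. Of 88 tested tRNA probes, 59 were higher and 5 lower. Their median log2 ratio was 0.81, a 1.75-fold rise, and the medians on the 2 arrays were 1.15 and 0.47. With the other slide's controls the tRNA median was -0.36, with 1 probe higher and 26 lower. Probes for snoRNA and scaRNA, which guide the modification of ribosomal and spliceosomal RNA, had 81 of 280 lower and 17 higher, with 182 not called, and a median of -0.18, with array medians of -0.20 and -0.18. As sets, tRNA and snoRNA with scaRNA each had an adjusted p of 0.994 in camera with an estimated correlation, though both were called at the preset correlation. The estimated correlation between tRNA probes was 0.53, against the preset 0.01. Counts of tRNA probes, here and in the other comparisons, are therefore not counts of independent tRNAs. The probes for PGK1, a glycolytic enzyme, rose by 0.71 ± 0.11 at the 5' end and by 0.79 ± 0.06 at the 3' end (log2, SD, n = 2), each with a limma adjusted p of 0.0023. The 5' probe also passed against all 4 controls (0.60, adjusted p = 0.014) and against the controls of the other slide (0.48, adjusted p = 0.0052), where the 3' probe gave 0.44 and 0.095 and did not pass. With control pairs averaged neither passed, at 0.60 and 0.44. The probes for GAPDH, another glycolytic enzyme, gave -0.29 and -0.30 and did not pass, with limma adjusted p of 0.061 and 0.057; each passed under 4 of the alternatives tried.

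Among the 15 classes tested in the knockout, camera at the preset correlation called tRNA (adjusted p = 7.9e-11) and snoRNA and scaRNA (adjusted p = 0.0043). The adjusted p of fry was 0.140 for tRNA and 0.137 for snoRNA and scaRNA. The catalogue series A 21, A 23, A 24 and A 32 had medians of 0.020, 0.068, 0.043 and 0.011 with an upward direction in camera but means of -0.044, -0.010, -0.032 and -0.055, and none of them was called. Of the 92 snRNA probes, 2 were higher and 9 lower, and of the 11 rRNA probes, 3 were higher and 0 lower. The E1A spike-in probes, which detect no human transcript, had mean log2 ratios of 0.62 and 0.18 on the same arrays. The 10 probes ran from -0.90 to 2.92 and from -1.25 to 2.63, with 7 and 5 of them above 0, and the labels do not say whether equal amounts were added to each sample. Without knockout replicate 1 the tRNA median was 0.47, and without either knockdown array, which share the estimate of spread, 30 tRNA probes were called higher. Against the controls of the other slide the median was -0.36, with 1 probe higher and 26 lower. Camera at the preset correlation then called the class in the downward direction (adjusted p = 9.7e-07). Against all 4 controls the tRNA median was 0.072, which was not called. The snoRNA and scaRNA call was lost with the scanner software's processed signals (median -0.16, adjusted p = 0.077) and against the controls of the other slide (median -0.053).

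**Figure D1:**
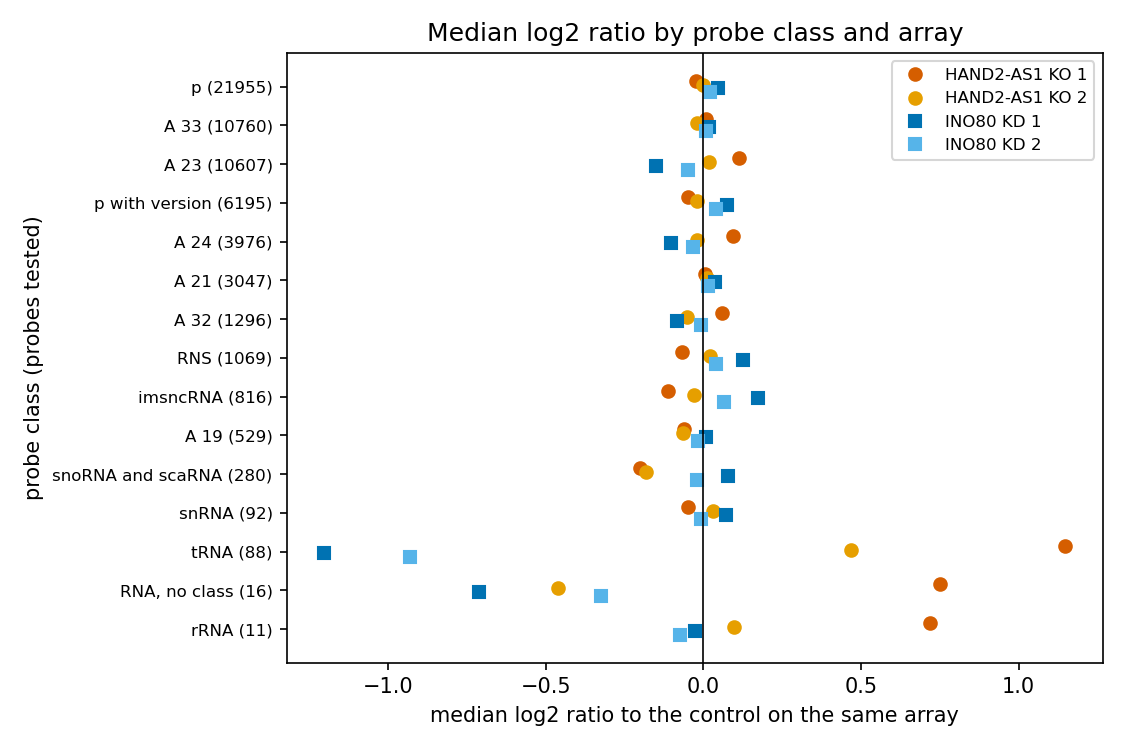
Median log2 ratio of the tested probes of each class with 10 or more tested probes, for the 2 knockout arrays (circles) and the 2 knockdown arrays (squares), each against the control on its own array; the number of probes is in parentheses. The tRNA medians lie at 1.15 and 0.47 in the knockout and at -1.20 and -0.93 in the knockdown.

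Of 60743 probes tested in the knockout, limma called 6604 higher and 9773 lower, 16377 in all (27.0%), against 24816 at an unadjusted p under 0.05. At least a 2-fold change was found for 1254 of the higher and 3036 of the lower probes. The highest probe, A_33_P3369401, rose by 5.18 (SE 0.18, adjusted p = 1.5e-04) and was 36.2-fold above control, with 5.12 and 5.24 on the 2 arrays. The lowest, A_23_P421379, fell by 6.59 (SE 0.13, adjusted p = 8.7e-05) and was 96.2-fold below control. Probes well above background in both controls of the slide and in neither knockout sample numbered 2504, and the reverse held for 367. Taken as lower bounds, 357 of the former were at least 2-fold lower and 19 of the latter at least 2-fold higher; these bounds are open to dye bias. Against all 4 controls 1556 probes were called, with control pairs averaged 0 (limma, 7157 at an unadjusted p under 0.05), and without either knockdown array 8417. The higher calls made up 40.3% of all calls, but 30.2% with median centring and 52.6% in the series matrix values, where the median over all probes moved to 0.11 from 0.0048. Against all 4 controls neither named probe was called, with 3.37 and -4.75, and against the controls of the other slide A_33_P3369401 gave 1.57 and A_23_P421379 gave -2.91.

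In the INO80 knockdown, tRNA probes were lower than in the controls of the same slide, with 68 of 88 lower and 0 higher. The median log2 ratio was -1.07, a 2.1-fold fall, and the array medians were -1.20 and -0.93. With the other slide's controls the tRNA median was 0.34, with 41 probes higher and 13 lower. In the class named imsncRNA, 161 of 816 probes were higher and 69 lower, with 586 not called and a median of 0.12. In the catalogue series A 23, 2344 of 10607 probes were lower and 1124 higher, with 7139 not called and a median of -0.097. With median centring this median was 0.011 while that of all probes moved to 0.087 from 0.0098, and camera at the preset correlation still called the series (adjusted p = 0.033). With an estimated correlation the adjusted p of camera was 0.973 for tRNA, imsncRNA and series A 23 alike. The snoRNA and scaRNA probes split into 56 higher and 60 lower, with a median of 0.030 and a mean of -0.068. The 3' probe of GAPDH fell by 0.49 ± 0.16 (log2, SD, n = 2; limma adjusted p = 0.012), whereas its 5' probe gave -0.16 ± 0.18 and did not pass. The 3' probe did not pass without knockdown replicate 1 (-0.37) or replicate 2 (-0.60), nor against all 4 controls (-0.35) or the controls of the other slide (-0.22). The 5' probe passed with median centring (-0.37, adjusted p = 0.022) and, in the other direction, against the controls of the other slide (0.48, adjusted p = 0.0065). The PGK1 probes gave 0.083 ± 0.053 at the 5' end and -0.24 ± 0.14 at the 3' end and did not pass, with limma adjusted p of 0.42 and 0.082. Against the controls of the other slide they gave 0.31 and 0.45 and both passed, with limma adjusted p of 0.018 and 0.0065.

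In the knockdown, camera at the preset correlation called tRNA (adjusted p = 4.1e-17), series A 23 (adjusted p = 0.022) and imsncRNA (adjusted p = 0.024). The adjusted p of fry was 0.415 for tRNA and 0.538 for both others. Without knockdown replicate 1 the median of series A 23 was -0.048 and that of imsncRNA 0.065, and neither was called. Against the controls of the other slide these medians were 0.051 and -0.034, and neither was called. Against all 4 controls they were -0.023 and 0.030, and neither was called. With no filter on dim probes the call of series A 23 was lost as well (-0.078, camera adjusted p = 0.055). Without either knockdown array 0 tRNA probes were called lower by limma, while the tRNA medians were -0.93 and -1.20. The E1A spike-in probes had mean log2 ratios of -1.11 and -0.64 on these arrays, with 2 and 4 of the 10 above 0. Against the controls of the other slide the tRNA median was 0.34, with 41 probes higher and 13 lower, and against all 4 controls it was -0.24, which was not called. Relative to the mean of controls 1 and 2, the median tRNA difference was 1.34 and 1.39 in controls 3 and 4, 0.23 and 0.37 in the knockdown samples and 1.07 and 0.48 in the knockout samples.

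**Figure D2:**
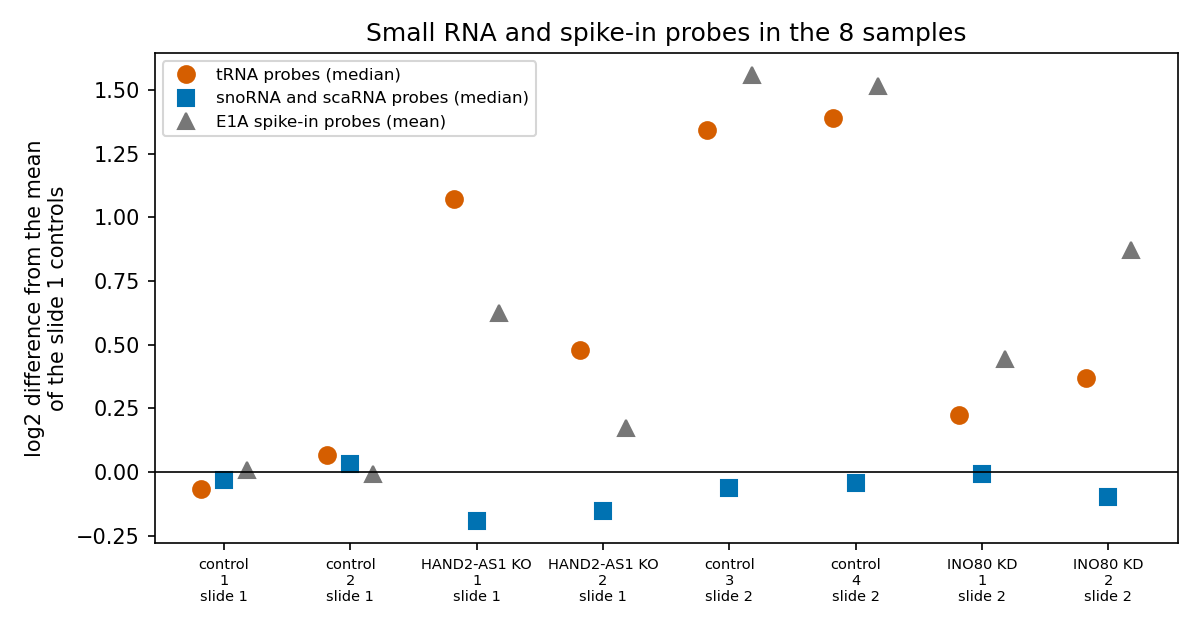
Log2 difference of each of the 8 samples from the mean of the slide 1 controls, as the median over tRNA probes (circles), the median over snoRNA and scaRNA probes (squares) and the mean over E1A spike-in probes (triangles). Controls 3 and 4 have the highest tRNA values, 1.34 and 1.39, and the highest E1A values, 1.56 and 1.51.

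In all, limma called 8389 probes higher and 8793 lower in the knockdown, 17182 of 60743 (28.3%), against 25622 at an unadjusted p under 0.05. At least a 2-fold change was found for 1385 of the higher and 2358 of the lower probes. The highest probe, p41150_v4, rose by 3.10 (SE 0.27, adjusted p = 0.0039) and was 8.6-fold above control, with 3.65 and 2.56 on the 2 arrays; against the controls of the other slide it was -0.37. The lowest was again A_23_P421379, which fell by 4.34 (SE 0.13, adjusted p = 0.0016), a 20.3-fold difference. Against the controls of the other slide it gave -8.02 and against all 4 controls -6.18. Without knockdown replicate 1 or replicate 2 neither named probe was called, with an adjusted p of 0.11 and 0.084 for each; A_23_P421379 then gave -4.54 and -4.14, and p41150_v4 gave 2.56 and 3.65. Probes well above background in both knockdown samples and in neither control of the slide numbered 3895, and the reverse held for 134. As bounds, 10 of the former were at least 2-fold higher and 70 of the latter at least 2-fold lower. With either knockdown array left out limma called 0 probes, against 12971 without replicate 1 and 15266 without replicate 2 at an unadjusted p under 0.05. Without either knockout array it called 25589, against all 4 controls 2612, with control pairs averaged 0 (8519 unadjusted), and against the controls of the other slide 27406. The higher calls made up 48.8% of all calls and 70.8% with median centring.

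The next comparison asked where the log2 ratios of the 2 perturbations differed, each taken against the controls of its own slide. It therefore includes any difference between those controls. The tRNA probes stood 4.07-fold apart at the median, a log2 difference of 2.03, with 64 of 88 higher in the knockout and 5 lower. All 59 tRNA probes that were higher in the knockout were lower in the knockdown. Of the imsncRNA probes, 167 of 816 had a lower ratio in the knockout than in the knockdown and 43 a higher one, with 606 not called and a median difference of -0.22. In series A 23, 2118 of 10607 were higher and 1322 lower, with 7167 not called and a median difference of 0.13. With median centring it was -0.036 while that of all probes was -0.17, and camera at the preset correlation still called the series (adjusted p = 0.0060). With an estimated correlation the adjusted p of camera was 0.858 for tRNA, imsncRNA and series A 23 alike. The PGK1 probes differed by 0.62 (SE 0.13, limma adjusted p = 0.012) at the 5' end and by 1.03 (SE 0.14, limma adjusted p = 0.0023) at the 3' end. The 5' difference did not pass without knockdown replicate 1 (0.59) or replicate 2 (0.66), with the processed signals (0.63) or in the series matrix values (0.59), and neither difference passed against all 4 controls (0.40 and 0.34). The GAPDH probes differed by -0.14 at the 5' end and 0.19 at the 3' end and did not pass. Against all 4 controls these differences were -0.77 and -0.081 and did not pass, and the 5' difference was positive with median centring (0.093), with the processed signals (0.26) and in the series matrix values (0.28).

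At the preset correlation camera called the difference for tRNA (adjusted p = 5.4e-20), imsncRNA and series A 23 (adjusted p = 0.0061 for each). The adjusted p of fry was 0.131, 0.154 and 0.393 in the same order. Without knockout replicate 1 and without knockdown replicate 1 the imsncRNA median was -0.17 and -0.15, that of series A 23 was 0.072 and 0.077, and neither was called. Against all 4 controls the median difference was -0.013 for imsncRNA and 0.023 for series A 23. Neither was called there by camera (adjusted p = 0.24 and 0.69). Without either knockdown array 0 tRNA probes were called by limma, and against all 4 controls the tRNA median was 0.37, which was not called (adjusted p = 0.082), whereas the same median with control pairs averaged was called (adjusted p = 0.048). In all, limma called the knockout ratio above the knockdown ratio for 7471 probes and below it for 9770, 17241 in total (28.4%). Of these, 3707 and 4250 differed by at least 2-fold. Between the perturbed samples themselves, within Cy5, limma called 657 probes. Between the control pairs of the slides, within Cy3, it called 38274, though the replicates of the controls also lay closer together. For the knockout ratio minus the knockdown ratio, 25577 probes had an unadjusted p under 0.05. With median centring the higher calls made up 22.7% in place of 43.3%, and the median over all probes moved to -0.17 from -0.041. With either knockdown array left out limma called 0 probes, against 15800 without replicate 1 and 17931 without replicate 2 at an unadjusted p under 0.05. With all 4 controls taken as 1 group it called 472, and with control pairs averaged 0 (7371 unadjusted).

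Across probes, the log2 ratios of the knockout and the knockdown correlated weakly, with a Pearson r of 0.21, a Spearman rho of 0.10 and a covariance of 0.062. In 100 simulations of unchanged samples, each array with its own control, r stayed within 0.016 of 0. These hold independent noise only and leave out a dye bias of the probe shared by the arrays. They therefore do not tell whether the observed r exceeds that of unchanged samples. Single knockout arrays correlated with single knockdown arrays at 0.064 to 0.31. Probes called lower in both comparisons numbered 2425, where independent lists would share 1415, and probes higher in both numbered 1506, where 912 would be shared. Probes higher in the knockout and lower in the knockdown numbered 1220, against 956 for independent lists, and the reverse pair 1025, against 1350. Both comparisons share the same estimate of spread for each probe, which favours calls in both. Independent lists therefore give no full value for no relation. Of the probes at least 4-fold lower, 771 in the knockout and 250 in the knockdown, 86 were shared, where independent lists would share 3.17. Of those at least 4-fold higher, 86 in the knockout and 33 in the knockdown, 0 were shared, where independent lists would share 0.047. With all 4 controls shared by both comparisons r was 0.63 and the covariance 0.14. Simulated unchanged samples against shared controls gave 0.33 and 0.0044, but these hold replicate noise only and leave out the difference between the controls of the slides (SD 0.68), so they give no full value for no change.

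**Figure D3:**
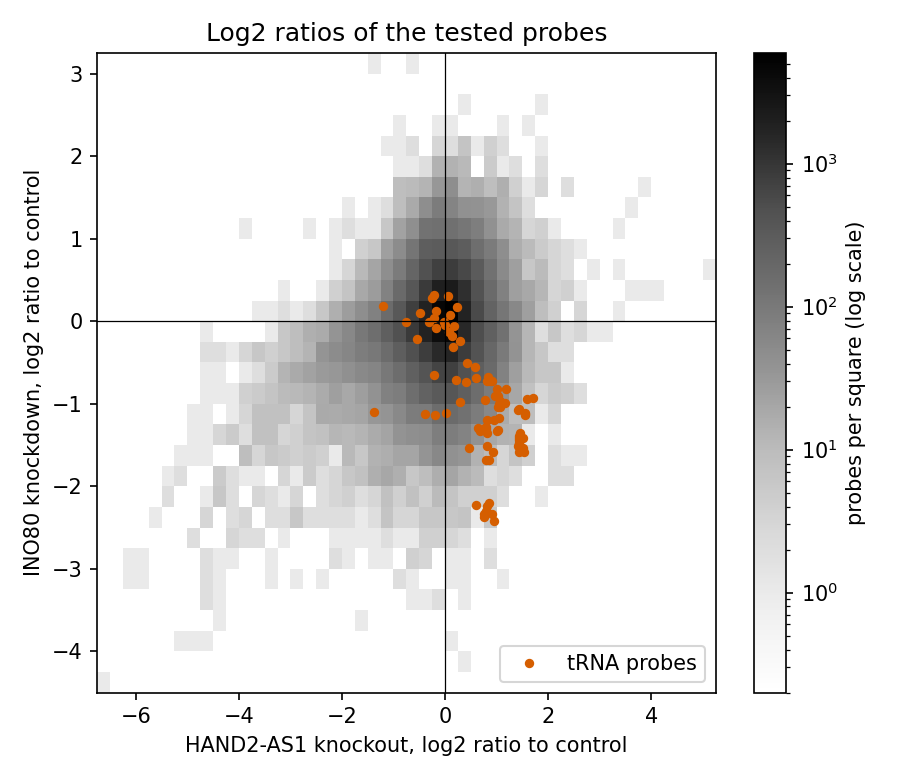
Log2 ratio to control of each tested probe in the HAND2-AS1 knockout (horizontal axis) and in the INO80 knockdown (vertical axis), as the number of probes per square on a log grey scale, with tRNA probes as orange points. Over all probes r was 0.21, and 59 of the 88 tRNA probes were called higher in the knockout and lower in the knockdown.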

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

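The tests of the tRNA pattern were chosen after its values had been seen, as was the comparison with the other slide's controls. The tRNA probes differed between the perturbations by a median of 2.03 (log2), called by camera on the difference itself at the preset correlation, but with an adjusted p of 0.858 at an estimated correlation and of 0.131 by fry. The tables argue against a carry-over of small RNA of every kind into controls 3 and 4: the upper quartile of the snoRNA and scaRNA shift between the controls of the slides was 0.36, below the lower quartile of 0.47 for tRNA, whose median shift was 1.34; vault RNA (median 0.68), rRNA (0.66) and RNA without a class in the name (0.44) were also higher there, so a carry-over of some kinds stays open. The fall in the knockdown may lie in its controls, since the median of the knockdown stood 0.34 above the controls of slide 1, a comparison that also spans dyes and slides; a knockdown low against every control would have stood below 0. Part of the pattern may follow a share of the input that the E1A spike-ins also track. Taking off each array's E1A ratio left 0.60 of the 1.87 between the means of the array medians. This is inside the 95% half-width of 0.68 that 2 arrays against 2 allow, so that share stays open. The labels also do not say whether equal amounts were added. Within an array the 10 E1A probes go both ways, but every one of them was lower on both knockdown arrays than on both knockout arrays. An effect of the perturbations on tRNA stays open and untested, because each perturbation lies on its own slide with its own controls.

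For 2 other probe classes the difference between the perturbations was called by camera at the preset correlation, at 0.13 for series A 23 and -0.22 for imsncRNA (median log2, knockout minus knockdown). Neither call held at an estimated correlation (adjusted p = 0.858 for each) or by fry (adjusted p = 0.393 and 0.154), or without replicate 1 of either perturbation. Against all 4 controls these medians were 0.023 and -0.013, and neither was called. Single probes were picked out because their difference passed its own test: 0.62 and 1.03 for the 5' and 3' probes of PGK1, 4.63 for A_33_P3369401, -2.24 for A_23_P421379 and -3.68 for p41150_v4 (log2, knockout ratio minus knockdown ratio). Each ratio is to its own slide's controls, and the named probes had been chosen as extremes of these ratios. Against the controls of slide 1, the knockdown gave -8.02 for A_23_P421379 and -0.37 for p41150_v4. The knockout gave -6.59 and -0.58 there, so the difference for A_23_P421379 turns the other way. Against those of slide 2, A_33_P3369401 gave 1.57 in the knockout and 0.55 in the knockdown. Among the 8 control probes for mouse and rat genes, which no comparison used, the 5' probe for mouse GAPDH had a mean log2 signal of 9.27 in the knockout samples, 9.14 and 9.40, above the highest control at 9.01. In the knockdown samples it was 9.46 and 8.80, and in controls 3 and 4 it was 7.75 and 7.54. It was picked out as the only one with both samples of a perturbation above every control, and others shifted more. On the knockout arrays the 5' probes for rat and mouse PGK1 had log2 ratios of 0.637 to 0.765, against 0.337 and 0.390 for mouse GAPDH. The 3' probe for rat PGK1 stood at 8.31 and 8.27 in controls 3 and 4, against 6.11 to 6.44 in the other samples.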

How the results depend on the processing

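The comparison with the other slide's controls and the fit with averaged control pairs were added after the data had been examined. Of the counts, correlation and tRNA medians under the alternatives, 87 held. Held means direction and side of the threshold kept, counts within 1.5-fold, or correlation within the spread between arrays. A further 21 counts or correlations moved by more, 5 tRNA medians lost a call and 3 changed sign. For other results 296 held, 48 lost a call, 12 gained one in the same direction, 22 changed sign and 19 counts moved by more. Log2 values cannot change where only the variance model or the other perturbation's arrays do, so these tallies overstate stability. Called probes numbered 4290, 3743 and 7957 for the knockout, the knockdown and their difference with a 2-fold minimum, and 8417 for the knockout with only its 2 arrays. Without the replicate block, with separate channels against all 4 controls, they numbered 1556, 2612 and 472, the correlation was 0.63, and the tRNA medians were 0.072, -0.24 and 0.37. There, and with control pairs averaged, the 5' GAPDH and 3' PGK1 probes turned to 0.16 and 0.10 in the knockdown and the 3' GAPDH difference to -0.081, none of them called. With control pairs averaged, limma called 0 in each comparison, the correlation was 0.63 and the tRNA medians were 0.072, -0.24 and 0.37, the last of them called (adjusted p = 0.048); fewer samples entered this fit, and 7157, 8519 and 7371 probes had an unadjusted p under 0.05. Against the other slide's controls the knockdown gave 27406 probes and a tRNA median of 0.34, and the knockout a tRNA median of -0.36. In the knockdown, these controls also turned imsncRNA to -0.034, series A 23 to 0.051 and p41150_v4 to -0.37, and the 5' GAPDH and 3' PGK1 probes to 0.48 and 0.45, which passed. Median centring turned series A 23 to 0.011 in the knockdown and -0.036 in the difference, where the medians of all probes were 0.087 and -0.17; the shift is common to all probes, and the series was still called (adjusted p = 0.033 and 0.0060). The 5' GAPDH difference turned to 0.093 with median centring, 0.26 with the processed signals and 0.28 in the series matrix values, not called. The cause was not tested where none is named.

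The replicate block by the labels' numbers pairs knockdown replicates 1 and 2 with controls 1 and 2 of the other slide; the deviations of these samples correlated at 0.15 across probes, those of the knockdown and its own array's controls at 0.14, and those of the knockout and its array's controls at 0.047, with 2 pairs each, so the numbers are not shown to pair the samples. Under this block 5091 probes differed between the perturbations, the correlation was 0.80, the tRNA difference was 0.37 (adjusted p = 0.026, 19 probes higher), and the knockdown gave 0.34 for tRNA, -0.034 for imsncRNA, 0.051 for series A 23, -0.37 for p41150_v4 and -8.02 for A_23_P421379. In the knockout 35 tRNA probes were called higher under it, in place of 59. The 5' GAPDH and 5' and 3' PGK1 probes passed in the knockdown at 0.48, 0.31 and 0.45, the 5' GAPDH difference passed at -0.77 (adjusted p = 0.0030), and the 3' GAPDH difference was -0.081, not called.

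With each array left out in turn, the counts ran from 8417 to 17284 for the knockout, from 0 to 25589 for the knockdown and from 0 to 22884 for the difference, the correlation from 0.10 to 0.29, and the tRNA medians from 0.47 to 1.15, from -1.20 to -0.93 and from 1.69 to 2.31. Where a perturbation kept 1 array, that array was assumed to vary like the pair of the other perturbation. The counts of 0 by limma came without a knockdown array, when the knockout pair alone set the spread, with 12971 and 15266 probes at an unadjusted p under 0.05 for the knockdown and 15800 and 17931 for the difference. Signal over background was lowest in controls 3 and 4, where the median raw intensity was 2.28 and 2.83 times the negative control, against 3.90 to 4.83 in the other samples. Alternatives that need gene names were not run.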

Other observations

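The tests of the differences between slides and of RNA degradation were chosen after the results had been seen, and the test on probes lower in both comparisons before. Among the smallest classes, 4 vault RNA probes, for RNA of the vault particle, had a median log2 ratio of 0.21 in the knockout with 1 higher, and of -0.38 in the knockdown with 2 lower. The 11 rRNA probes had medians of 0.24 in the knockout, with 3 higher, and of -0.050 in the knockdown, with 2 higher and 2 lower. The 1 tested ribozyme probe was lower in the knockout, at -0.55, and gave 0.11 in the knockdown, where it did not pass. The 16 tested RNA probes without a class in their names had medians of 0.75 and -0.46 on the knockout arrays, and none was called there.

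The controls of the slides differed more than the perturbed samples did. The standard deviation over probes was 0.68 between the controls of slides 1 and 2 and 0.41 between the knockdown and knockout samples, and 7842 against 2035 probes stood at least 2-fold apart, both within a dye. The tables argue against a slide or hybridization effect common to both channels as the whole cause, since the slide differences in Cy3 and Cy5 correlated at 0.26 across probes. Degraded RNA in controls 3 and 4 stays open, since the 3' minus 5' signal differed there from the controls of slide 1 by -0.37 for GAPDH and by 0.47 for PGK1, and 2 genes that go opposite ways decide nothing. A Cy3 labelling difference between the slides or a different control culture may lie behind it, and neither was tested.

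Probes lower in both comparisons exceeded independent lists, with 2425 against 1415, though a shared estimate of spread for each probe favours calls in both. For a dye bias of the probe, equal on all arrays, as the whole change, under 10% of these probes were predicted to differ between the perturbations. The share was 39.6%, against 28.4% of all tested probes. The share thus lay above the prediction. The comparison between the perturbations includes the difference between the control pairs of the slides, so probes that share a dye bias can still differ through their controls. It also uses the same estimate of spread for each probe, which favours a call there as well. The test does not decide whether the shared fall is a dye bias. Among the 86 probes at least 4-fold lower in both, 62.8% differed, and among the 1506 probes higher in both it was 14.0%. Neither share excludes such a bias as part or all of the change. A dye bias as part or all of the change, or one unequal between slides, stays open without swapped dyes, as does an effect shared by the perturbations.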
